A study of Arabidopsis thaliana with 22 samples.

How the data were processed

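Total RNA (150 ng) of 10-day-old seedlings, grown at 22 °C in continuous light of 120 µE per the labels, was labelled with Cy3 and hybridised to Agilent 44K arrays, 1 sample per array. The intensity values used, gProcessedSignal, are deposited as made by Agilent Feature Extraction, background-subtracted and detrended within the array with no normalization between arrays, per the file headers. The headers name version 10.10.1.1, the submitters' processing notes version 9.1. The deposited table of all samples holds the same values (22 of 22 columns identical on every spot). The design text of the series gives 3 biological samples per genotype in 2 batches prepared and hybridised separately. Whether the samples of a genotype were grown apart is not given, so p-values measure only the spread between these samples. The overexpressed proteins carry a YFP and HA tag per the labels. A wild type and a GNLox sample of batch 1 are not analysed here.

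Each array holds 45220 spots, 43803 of them gene spots of 43603 probes. Spots marked by Feature Extraction as non-uniform or population outliers were left out (4 to 505 per array), and 0 spots were saturated. Signals were taken to log2 and the array's 75th percentile of gene spots was subtracted. A probe was kept if well above background on every array of at least 1 group, and the brightest kept probe stood for its gene, with 6718 genes having several. This gave 27491 genes, 23951 with a locus and 3540 known by an accession alone, of which 1286 had a left-out spot. A reference table of loci served only for names, matching 23665 loci and giving a symbol to 9697. No genome build was needed. Correlations between arrays were 0.941 to 0.996.

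Differences were tested with limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0, figures with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9), as moderated tests from 1 fit of 8 group means over 22 arrays with 14 residual degrees of freedom and 1.91 prior degrees. A gene is called at an adjusted p (Benjamini-Hochberg, within the comparison) under 0.05, and counts of calls changed at least 2-fold are given beside. Comparisons, alternatives and gene lists were chosen before the data were examined, apart from those named as added. GNL_LLM_AAAox against GNLox and GNCox against GNLox cross the batches and are differences of the differences from each batch's wild type. Every adjusted p of a gene or list in the text is from limma. The "at least" fold puts the level at which a spot of that array counts as well above background in place of dim values. Differences across batches were also computed with that level, added after the data were seen.

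The 21 gene lists were fixed from general knowledge with 387 members. Of these 4 were dropped because locus and name disagreed in the reference table (383 kept, 380 measured, 1 in more than 1 list). Lists were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over 21 lists, and members were also adjusted over the list alone. Genes named in the text follow a rule fixed beforehand. It takes all B-GATA genes and the 6 largest rises and falls per comparison with wild type (5 between lines) among called genes with a symbol, above background on every array of the higher group and without overlap between groups. It also takes, in the comparisons with wild type and in GNC_LLM_AAAox against GNCox, up to 3 called members with the largest change in each list that passed or had at least 5 called members.

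Each result was recomputed with quantile normalization, eBayes with trend and robust, no filter, probes well above background on every array, the mean of all probes, arrays of the same batch only, replicate label as a block, slide as a random block, and each array left out. A planned normexp background correction lacked its mean-signal column and was fitted on the median signal. It broke on 4 arrays (16 to 4898 calls per comparison), so a fit without spots whose local background is over 50 brighter than the spot (at most 19 per array) was added. Slide as a fixed block was added as well, because each of the 6 slides holds 2 groups. For GNC_LLM_AAAox against GNCox it equals the difference within the slide that holds 2 arrays of each. For GNLox and GNCox against wild type, GATA17ox against GNLox and BdGATA6ox against GATA17ox the shared slide holds 1 array of 1 group, and the other comparisons run over such single arrays.

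The pipeline was tested on simulated data of 26205 genes. At 1.5-, 2- and 4-fold it recovered 43.3%, 74.6% and 95.5% for GNLox, 50.7%, 77.6% and 89.4% for GATA17ox, 47.8%, 77.6% and 93.9% for BdGATA6ox, 41.8%, 88.1% and 97.0% for GNCox. GNC_LLM_AAAox gave 55.2%, 73.1% and 95.5% and GNL_LLM_AAAox 44.8%, 77.6% and 93.9%, of 67, 67 and 66 changed genes each. False calls were 7 of 149, 6 of 151, 5 of 151, 11 of 162, 6 of 155 and 4 of 148. Of 21 sets of 20 genes only the 1 shifted by 0.5 passed. Fewer genes changed than in the lines, and the real arrays correlate within slides (0.352) and differ in spread by group. These rates need not hold for the real calls or lists.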

Results

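Transcript levels of 10-day-old Arabidopsis thaliana seedlings were measured with 1-colour arrays, 22 in 8 groups prepared in 2 batches. Batch 1 holds the wild type (n = 2), GNLox (n = 2), GATA17ox (n = 3) and BdGATA6ox, which carries a Brachypodium distachyon gene (n = 3). Batch 2 holds the wild type, GNCox, GNC_LLM_AAAox and GNL_LLM_AAAox (n = 3 each). In the last pair of lines the leucine-leucine-methionine (LLM) motif is changed to 3 alanines. The signal at the 75th percentile of an array was 1285 to 3695, lowest in GNLox (1285 and 1650) and GATA17ox (1290 to 1338), and 76.1% to 83.6% of gene spots were well above background. Arrays of 1 group correlated at 0.982 to 0.983 in WT_batch1 and GNLox and at 0.991 to 0.996 in GNCox and the LLM-mutated lines.

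Values below are log2 differences ± SE from limma with adjusted p over all genes of the comparison. Each group has 2 or 3 arrays, so their number limits the precision. The strongest or largest single changes are those among genes with a symbol, and unnamed loci that changed more are left out. Slide-blocked values have slide as a fixed block. All but those of GNC_LLM_AAAox against GNCox rest on single arrays that link the slides. Normexp-corrected values have a normexp background correction without spots under a bright background. "At least" folds are given where no array of the dimmer group was well above background, with the arrays' background level in place of the dim values. Comparisons across batches have no such bound, so the difference with that level is given instead. With 3 and 3 arrays, chance leaves groups without overlap in 10% of cases, more with fewer arrays.

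GNL codes for a B-class GATA factor of greening. Its transcript rose in GNLox (3.73 ± 0.15, adjusted p = 5.54e-10, n = 2 and 2), where its group mean was 1.36 (SD 0.29) against -2.36 (SD 0.15) in wild type. It rose as well in GNL_LLM_AAAox (5.12 ± 0.13, adjusted p = 4.84e-13, n = 3 and 3), and GATA17 rose in GATA17ox (1.58 ± 0.13, adjusted p = 1.67e-07, n = 3 and 2). GNC has 2 probes that part. Probe A_84_P827727, used in the tests, rose in GNCox (1.13 ± 0.16, adjusted p = 1.5e-05) and GNC_LLM_AAAox (1.56 ± 0.16, adjusted p = 1.3e-05). Probe A_84_P212728 fell in both (-1.41 and -0.97), and the mean of both probes gave -0.14 in GNCox. BdGATA6 has no Arabidopsis probe, so its transgene was not measured. GNC_LLM_AAAox also had more GNL transcript than wild type (1.69 ± 0.13, adjusted p = 9.9e-07), whereas GNL in GNCox was 0.03 ± 0.13 (adjusted p = 0.86). GATA16, a relative of GNC, fell in GNLox (-3.11 ± 0.20, adjusted p = 4.02e-08, at least 2.90-fold) and GNCox (-1.36 ± 0.16, adjusted p = 3.69e-06). In GATA17ox it fell too (-2.96 ± 0.18, adjusted p = 1.24e-08, at least 2.46-fold), but was at 0.00089 when normexp-corrected.

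**Figure D1:**
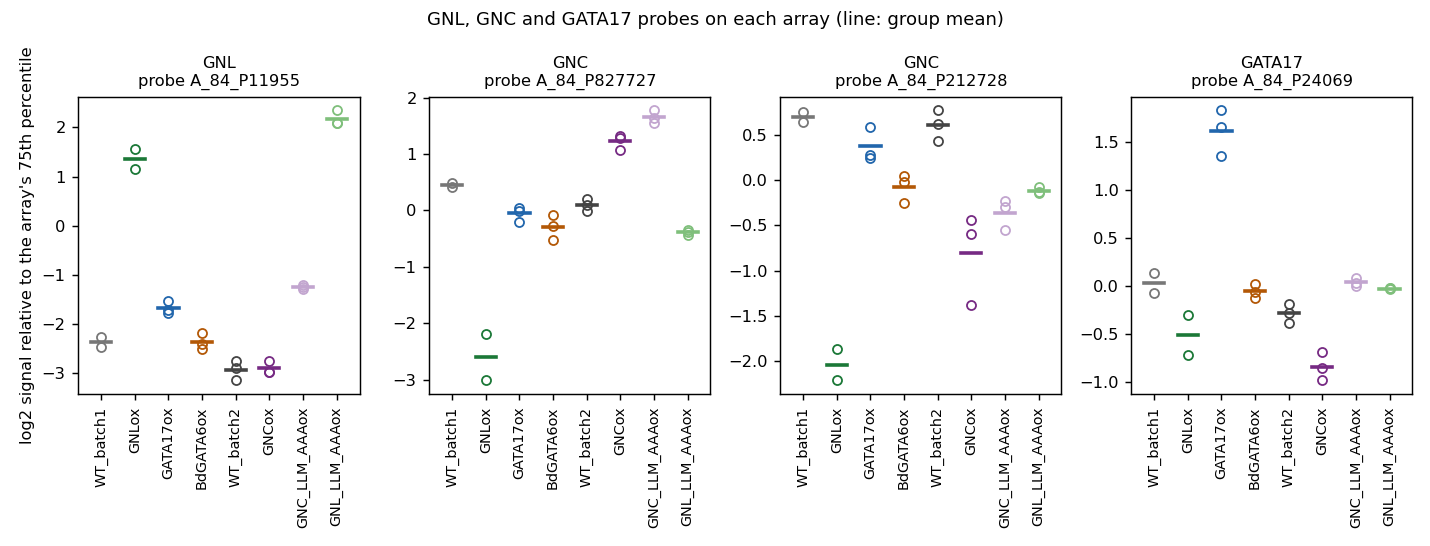
Signal of the GNL probe, both GNC probes and the GATA17 probe on each of 22 arrays by group, log2 relative to the array's 75th percentile, with group means as lines. GNL stands at 1.36 in GNLox against -2.36 in the wild type of batch 1, and GNC probe A_84_P212728 at -0.81 in GNCox against 0.61 in the wild type of batch 2.

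Against their wild types, 13186 genes changed in GNLox (3001 at least 2-fold), 15027 in GATA17ox (3580) and 8660 in BdGATA6ox (1748). In batch 2 it was 15621 in GNCox (3071), 3100 in GNC_LLM_AAAox (725) and 4862 in GNL_LLM_AAAox (999). With arrays of the same batch only, calls were 8349, 11061, 4207, 18149, 4866 and 7861, lower in batch 1 and higher in batch 2. Counts thus do not compare across batches. The slide-blocked counts were 13586, 11453, 3477, 14534, 2768 and 1891, and 3614, 4796, 1756, 4288, 1045 and 945 at least 2-fold. FT, the transcript of the mobile flowering signal, was lower in GNLox, GATA17ox, BdGATA6ox, GNCox and GNL_LLM_AAAox.

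**Figure D2:**
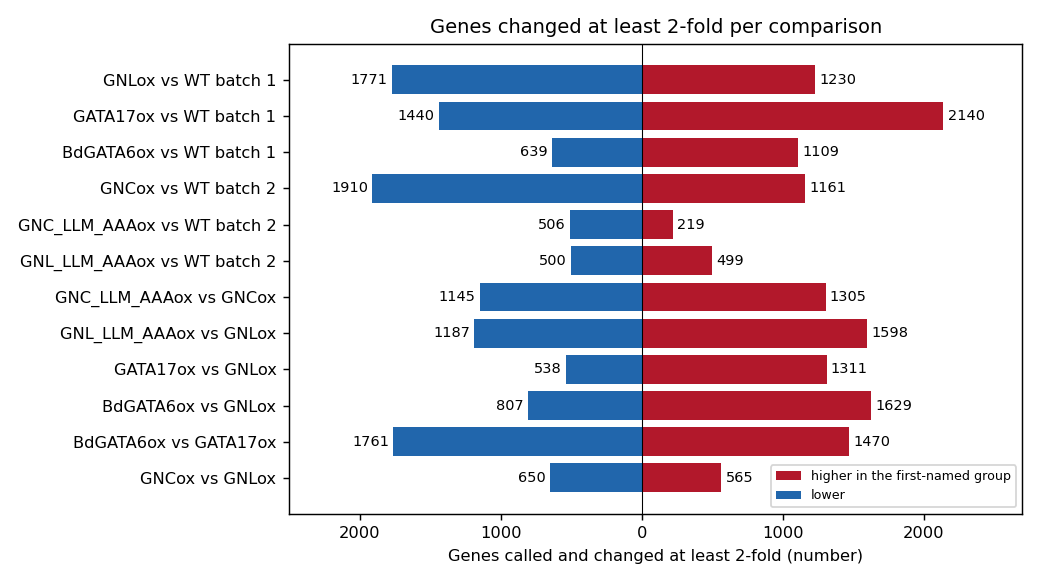
Number of genes changed at least 2-fold with adjusted p under 0.05 in each of 12 comparisons, higher in red and lower in blue. GNCox had 1161 higher and 1910 lower (37.8% higher, 47.6% normexp-corrected), and GNC_LLM_AAAox 219 higher and 506 lower (30.2% higher, 13.5% slide-blocked).

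GNLox was compared with the wild type of batch 1 (n = 2 and 2). PUM7, coding for a Pumilio RNA-binding protein, rose most (9.60 ± 0.60, adjusted p = 3.04e-08, at least 182-fold). NATA1, an acetyltransferase of ornithine (8.86 ± 1.99, adjusted p = 0.00186), and the terpene synthase TPS04 (7.27 ± 1.71, adjusted p = 0.00264, at least 41.3-fold) followed. MRD1 rose too (5.29 ± 0.31, adjusted p = 1.87e-08). M17, a late-embryogenesis transcript, rose (5.19 ± 1.3, adjusted p = 0.00441), a call that ended without WT_batch1 replicate 1 (4.18, adjusted p = 0.057). The strongest falls were JAL31 of the jacalin lectins (-5.70 ± 0.39, adjusted p = 6.69e-08, at least 24.2-fold), HAP13 (-5.59 ± 1.59, adjusted p = 0.00903) and the cineole synthase TPS-CIN (-5.16 ± 0.25, adjusted p = 2.23e-09). CWINV5, a cell wall invertase, fell too (-5.01 ± 0.93, adjusted p = 0.000462, at least 8.37-fold).

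B-GATA genes in GNLox fell for 8 of 11 and rose for 1, the transgene GNL (8 and 1 over the list alone), median -0.65 (slide-blocked -0.77). The B-GATA list passed at adjusted p = 0.00217 (0.608 with an estimated correlation). GNC (-3.05 ± 0.19, adjusted p = 3.45e-08) and GATA15 (-1.37 ± 0.15, adjusted p = 4.7e-06) fell beside GATA16. In chloroplast development and division 9 of 16 rose and 0 fell (10 and 1 over the list alone), with a median of 0.44 (slide-blocked 0.41) and no pass as a list (adjusted p = 0.0585). ARC6, a factor of plastid division (0.77 ± 0.10, adjusted p = 1.75e-05), and MINE1, which places the division ring (0.81 ± 0.13, adjusted p = 0.000139), were among them. In defence 11 of 19 rose and 2 fell (13 and 3 over the list alone), led by THI2.1, a thionin (3.57 ± 0.68, adjusted p = 0.000564). PDF1.2b, a plant defensin, rose (3.57 ± 1.02, adjusted p = 0.00882), a call that ended without WT_batch1 replicate 1 (3.25, adjusted p = 0.064). GA2OX1, which inactivates gibberellins (-1.81 ± 0.17, adjusted p = 1.25e-06), and ARR5, a cytokinin response regulator (-1.08 ± 0.08, adjusted p = 2.62e-07), fell. GH3.6, an auxin-conjugating enzyme, fell (-1.12 ± 0.09, adjusted p = 3.24e-07). HFR1, which restrains shade growth, fell (-1.97 ± 0.28, adjusted p = 5.16e-05), and PIL1 of the same pathway rose (1.80 ± 0.12, adjusted p = 4e-08). FT fell (-2.22 ± 0.64, adjusted p = 0.0094), a call that ended without WT_batch1 replicate 1 (-1.92, adjusted p = 0.077).

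Direction depended on scaling for several lists in GNLox. Of 32 photosystem and antenna genes 15 rose and 4 fell (median 0.32), but quantile normalization turned the median to -0.09 and the test to lower (adjusted p = 0.0439). The Calvin cycle median of 0.05 became -0.27 there (adjusted p = 0.0439). The flavonoid list had a positive median and mean (0.05, 0.19) with a test toward lower. Medians of cytokinin response, cell expansion, light signalling and flowering time, all negative, were positive when normexp-corrected. Among all calls 57.6% were higher (73.8% normexp-corrected), and among the 2-fold calls 41.0% (59.2%).

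GATA17ox was set against the same wild type (n = 3 and 2). Seed storage transcripts rose for 10 of 10 and fell for 0 (10 and 0 over the list alone), median 4.08 (slide-blocked 4.5). The seed storage list passed at adjusted p = 0.0124 (adjusted p = 0.775 with an estimated correlation). Among them were the cruciferins CRC (8.37 ± 2.14, adjusted p = 0.00372) and CRA1 (6.83 ± 1.41, adjusted p = 0.000745) and the albumin SESA1 (5.21 ± 1.22, adjusted p = 0.00203, at least 11.1-fold). Slide-blocked, CRC, CRA1 and SESA1 were 10.02, 6.34 and 5.26 and their calls ended (adjusted p = 0.0897, 0.107 and 0.107). CRC was also lost without WT_batch1 replicate 1 (6.05, adjusted p = 0.081). LCR67, a defensin-like peptide (9.34 ± 0.74, adjusted p = 1.11e-07, at least 189-fold) and SESA5 (8.74 ± 1.46, adjusted p = 0.000126, at least 102-fold) were the strongest rises. M17 (7.74 ± 1.19, adjusted p = 7.76e-05) and the peroxygenase ATPXG2 (6.58 ± 0.75, adjusted p = 3.77e-06) rose with them. Of genes with a symbol FT fell most (-4.43 ± 0.58, adjusted p = 1.43e-05, at least 4.51-fold), followed by CYP71B22 (-4.30 ± 0.41, adjusted p = 6.89e-07, at least 4.86-fold). NRT2.6, of the nitrate transporters (-4.03 ± 1.03, adjusted p = 0.00363, at least 4.89-fold), and CWINV5 (-3.76 ± 0.85, adjusted p = 0.00157, at least 7.11-fold) fell. Both calls ended when slide-blocked (-4.87 and -3.72).

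FLC, a repressor of flowering, rose in GATA17ox (1.88 ± 0.21, adjusted p = 2.82e-06). IAA29, an auxin-inducible repressor (2.27 ± 0.17, adjusted p = 8.38e-08), and GA20OX1, of gibberellin synthesis (1.5 ± 0.22, adjusted p = 3.33e-05), rose. COR15A, a chloroplast protein of cold tolerance, rose (2.84 ± 0.25, adjusted p = 3.29e-07) in a list of 17 with 8 higher and 1 lower. VSP2, a jasmonate marker (-3.43 ± 0.41, adjusted p = 5.08e-06), and LDOX, of anthocyanin synthesis (-1.51 ± 0.19, adjusted p = 1.08e-05), fell. ARC6 rose (0.60 ± 0.09, adjusted p = 4.22e-05). Photosystem and antenna genes were split, 7 higher and 9 lower of 32, with PSAL (-1.47 ± 0.22, adjusted p = 5.24e-05) and LHCA2 (-1.24 ± 0.14) lower. Their median was -0.02, and -0.26 after quantile normalization, where the list passed (adjusted p = 9.18e-06). RBCS1A of the Calvin cycle (0.69, higher) turned to -0.05 there. RBCS1A was not called without WT_batch1 replicate 1 (0.36, adjusted p = 0.21) or slide-blocked (0.91). When normexp-corrected the B-GATA median went from -0.27 to 0.00 and the flowering median from -0.05 to 0.17. Median, mean and test parted in sign for cell cycle (-0.24, 0.12, lower), flavonoid (0.07, -0.12, lower) and cell expansion genes (0.09, 0.02, lower). The median over all genes was 0.11 here. Of the calls 59.7% were higher (71.9% normexp-corrected), and of the 2-fold calls 59.8% (73.8%).

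BdGATA6ox was set against the same wild type (n = 3 and 2). ATPXG2 (6.99 ± 0.75, adjusted p = 8.94e-06), LTP4, a lipid transfer protein (6.75 ± 0.58, adjusted p = 1.03e-06), and SESA5 (6.64 ± 1.46, adjusted p = 0.00285, at least 23.8-fold) were the strongest rises. ECP63 (6.35 ± 0.66, adjusted p = 6.3e-06), ICL, an enzyme of lipid breakdown (6.09 ± 0.99, adjusted p = 0.000306), and OLEO2, an oil body protein (6.01 ± 0.67, adjusted p = 1.21e-05), rose too. EDA34 fell (-3.93 ± 0.49, adjusted p = 3.11e-05, at least 4.06-fold). Falls of NRT2.6 (-5.22 ± 1.03, adjusted p = 0.00133, at least 9.16-fold) and PCC1 (-4.87 ± 1.23, adjusted p = 0.00705) ended as calls when slide-blocked (-6.39 and -0.18). PCC1 was not called without WT_batch1 replicate 1 either (-4.41, adjusted p = 0.057). Seed storage transcripts rose for 6 of 10 and fell for 0 (6 and 0 over the list alone), median 4.52 (slide-blocked 2.99). The seed storage list passed at adjusted p = 0.00477 (0.336 with an estimated correlation). EM1 was among them (6.02 ± 1.12, adjusted p = 0.00105). Abscisic acid and cold genes rose for 6 of 17 and fell for 0 (6 and 0 over the list alone), median 0.43 (slide-blocked 0.90). The abscisic acid list passed at adjusted p = 0.00477 (0.336 with an estimated correlation). COR15A (3.58 ± 0.25, adjusted p = 1.42e-07) and ABI5, a factor of abscisic acid signalling (2.81 ± 0.25, adjusted p = 1.48e-06), stood out.

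Flowering genes in BdGATA6ox fell for 10 of 23 and rose for 0 (12 and 0 over the list alone), median -0.26 (slide-blocked -0.45). The flowering list passed at adjusted p = 0.00477 (0.336 with an estimated correlation). FT was among them (-2.45 ± 0.58, adjusted p = 0.00487), at -3.50 and not called when slide-blocked (adjusted p = 0.054). Stomatal lineage genes fell for 6 of 11 and rose for 0 (6 and 0 over the list alone), median -0.38 (slide-blocked -0.40). The stomatal list passed at adjusted p = 0.00834 (0.336 with an estimated correlation). EPF2, a peptide that limits stomata, fell (-0.65 ± 0.10). Photosystem and antenna genes fell for 14 of 32 and rose for 0 (16 and 0 over the list alone), median -0.28 (slide-blocked 0.11). The photosystem list passed at adjusted p = 8.68e-06 (0.376 with an estimated correlation). The slide-blocked test was far from passing (adjusted p = 0.855), and LHCB2.3 (-0.70 ± 0.16, adjusted p = 0.00427) was at -0.42 there (adjusted p = 0.44). LHCB2.3 was not called without WT_batch1 replicate 3 (-0.50, adjusted p = 0.073). B-GATA genes fell for 4 of 11 and rose for 0 (6 and 0 over the list alone), median -0.26 (slide-blocked -0.57). The B-GATA list passed at adjusted p = 0.033 (0.376 with an estimated correlation). GNC fell most (-0.75 ± 0.18, adjusted p = 0.00462). Chlorophyll biosynthesis genes fell for 6 of 23 and rose for 1 (6 and 1 over the list alone), median -0.16 (slide-blocked -0.23). The chlorophyll list passed at adjusted p = 0.00834 (0.376 with an estimated correlation). PORA, a protochlorophyllide reductase, was the exception (1.49 ± 0.53, adjusted p = 0.0412), reversed to -1.97 when slide-blocked and not called without WT_batch1 replicate 3 (1.02, adjusted p = 0.28).

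Calvin cycle genes in BdGATA6ox fell for 3 of 15 and rose for 0 (3 and 0 over the list alone), median -0.14 (slide-blocked -0.20). The Calvin cycle list passed at adjusted p = 0.0372 (0.376 with an estimated correlation). After quantile normalization their median was -0.02 (adjusted p = 0.817). Nitrogen genes fell for 6 of 15 and rose for 0 (6 and 0 over the list alone), median -0.32 (slide-blocked -0.14). The nitrogen list passed at adjusted p = 0.0372 (0.336 with an estimated correlation). GLN1;2, a glutamine synthetase, was at -0.51, slide-blocked -0.32 and not called. Light signalling genes fell for 9 of 19 and rose for 1 (10 and 1 over the list alone), median -0.25 (slide-blocked 0.06). The light signalling list passed at adjusted p = 0.0213 (0.336 with an estimated correlation). PIL1 was the exception that rose (1.33 ± 0.11, adjusted p = 5.21e-07). Flavonoid genes rose for 6 of 15 and fell for 1 (7 and 1 over the list alone), median 0.46 (slide-blocked 0.69). The flavonoid list passed at adjusted p = 0.0409 (0.545 with an estimated correlation). PAP2, a regulator of anthocyanin, rose (2.38, at least 1.37-fold) and was at 1.43 and not called when slide-blocked. Cell expansion genes had a median of -0.05 and a mean of 0.15. Of all calls 53.5% were higher (40.7% normexp-corrected, 41.8% without a filter), and of the 2-fold calls 63.4% (42.7% without a filter).

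GNCox was compared with the wild type of batch 2 (n = 3 and 3). Chlorophyll biosynthesis genes rose for 18 of 23 and fell for 0 (19 and 0 over the list alone), median 0.53 (slide-blocked 0.54). The chlorophyll list passed at adjusted p = 9.28e-05 (adjusted p = 0.281 with an estimated correlation). CHLI1 (0.84 ± 0.07, adjusted p = 1.51e-07) and CHLD (0.77 ± 0.09), subunits of magnesium chelatase, were among the strongest. Genes of chloroplast development and division rose for 12 of 16 and fell for 1 (12 and 1 over the list alone), median 0.62 (slide-blocked 0.74). The chloroplast list passed at adjusted p = 0.00061 (adjusted p = 0.281 with an estimated correlation). Plastid division led it with ARC6 (1.02 ± 0.08, adjusted p = 6.23e-08), ARC3 (1.03 ± 0.10, adjusted p = 4.86e-07) and FTSZ2-1, of the division ring (1.03 ± 0.10, adjusted p = 4.36e-07). Calvin cycle genes rose for 13 of 15 and fell for 0 (14 and 0 over the list alone), median 0.42 (slide-blocked 0.40). The Calvin cycle list passed at adjusted p = 0.000188 (adjusted p = 0.281 with an estimated correlation). HCEF1 (0.79 ± 0.09) and FBA1 (0.78 ± 0.08) rose most. Photosystem and antenna genes rose for 14 of 32 and fell for 0 (14 and 0 over the list alone), median 0.24 (slide-blocked 0.08). The photosystem list passed at adjusted p = 0.0168 (adjusted p = 0.578 with an estimated correlation). Quantile normalization turned that median to -0.09 (adjusted p = 0.186).

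Early auxin response genes in GNCox fell for 21 of 29 and rose for 4 (21 and 4 over the list alone), median -0.85 (slide-blocked -1.01). The auxin list passed at adjusted p = 9.28e-05 (adjusted p = 0.281 with an estimated correlation). SAUR9 (-2.11 ± 0.19, adjusted p = 2.44e-07) and SAUR19 (-1.27 ± 0.18), small auxin-up RNAs of growing tissue, were among them. Cytokinin response genes fell for 9 of 19 and rose for 2 (9 and 2 over the list alone), median -0.34 (slide-blocked -0.41). The cytokinin list passed at adjusted p = 0.0371 (adjusted p = 0.332 with an estimated correlation). ARR3, a response regulator, fell (-1.56 ± 0.24). Cell expansion genes fell for 11 of 18 and rose for 2 (11 and 2 over the list alone), median -0.69 (slide-blocked -0.81). The cell expansion list passed at adjusted p = 0.0216 (adjusted p = 0.332 with an estimated correlation). PRE5 fell (-1.64 ± 0.16) while XTH22, a wall-loosening enzyme, rose (1.54 ± 0.22). Root markers fell for 16 of 23 and rose for 0 (17 and 1 over the list alone), median -0.65 (slide-blocked -0.81). The root marker list passed at adjusted p = 0.00416 (adjusted p = 0.332 with an estimated correlation). DR4, a protease inhibitor of roots (-1.59 ± 0.16, adjusted p = 5.46e-07), and PLT1, a root stem cell factor (-1.17 ± 0.15), fell. B-GATA genes fell for 7 of 11 and rose for 1, the transgene GNC (7 and 1 over the list alone), median -0.56 (slide-blocked -0.81). The B-GATA list passed at adjusted p = 0.0226 (adjusted p = 0.332 with an estimated correlation). GATA15 fell with GATA16 (-0.98 ± 0.12). Seed storage transcripts rose for 8 of 10 and fell for 0 (8 and 0 over the list alone), median 2.87 (slide-blocked 2.97). The seed storage list passed at adjusted p = 0.016 (adjusted p = 0.332 with an estimated correlation). OLEO1 rose (3.95 ± 0.75, adjusted p = 0.000273). CRC (6.68 ± 1.91, adjusted p = 0.00687) and CRA1 (4.61 ± 1.26, adjusted p = 0.00499) rose too, and their calls ended when slide-blocked (5.69 and 3.95).

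The other 11 lists did not pass in GNCox. Their higher and lower counts were 4 and 4 of 15 for nitrogen (adjusted p = 0.773), 9 and 3 of 15 for starch (adjusted p = 0.0753) and 5 and 10 of 24 for gibberellin (adjusted p = 0.244). Light signalling had 5 and 11 of 19 (adjusted p = 0.0705), the clock 5 and 1 of 15 (adjusted p = 0.411) and flowering 5 and 11 of 23 (adjusted p = 0.0712). Flavonoid genes had 9 and 1 of 15 (adjusted p = 0.123), abscisic acid and cold 2 and 7 of 17 (adjusted p = 0.229) and defence 7 and 5 of 19 (adjusted p = 0.741). Stomatal lineage had 3 and 1 of 11 (adjusted p = 0.244) and cell cycle 2 and 1 of 11 (adjusted p = 0.79). Nitrogen genes had a median of 0.01 (-0.18 after quantile normalization), a mean of -0.12 and a test toward higher. HFR1 fell (-2.45 ± 0.23, adjusted p = 3.26e-07), and ELIP2, a light stress protein of the thylakoid, rose (2.03 ± 0.21, adjusted p = 1e-06). PGM1 of starch synthesis rose (1.05 ± 0.12). GA20OX1 (-1.35 ± 0.19), CBF3, a cold-response factor (-1.99 ± 0.23), and VSP2 (-2.51 ± 0.36) fell.

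FT fell in GNCox (-3.55 ± 0.52, adjusted p = 2.52e-05, at least 6.62-fold), and FUL, a floral regulator (-1.79 ± 0.27), with it. Beside CRC the largest rises were SESA5 (8.44 ± 1.3, adjusted p = 4.14e-05, at least 80.7-fold), HSD1 (5.58 ± 1.05, adjusted p = 0.000252) and LCR67 (5.49 ± 0.66, adjusted p = 3.71e-06, at least 19.0-fold). ATPXG2 (5.38 ± 0.67, adjusted p = 5.23e-06, at least 12.9-fold) and MRD1 (5.34 ± 0.25, adjusted p = 6.58e-10) followed. CWINV5 (-5.42 ± 0.76, adjusted p = 1.67e-05) and CYP712A1 (-3.41 ± 0.37, adjusted p = 1.35e-06) fell. AGL14, a MADS factor of roots (-3.30 ± 0.45, adjusted p = 1.22e-05), and SEN1, a dark-induced transcript (-3.23 ± 0.42, adjusted p = 7.98e-06), fell too.

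**Figure D3:**
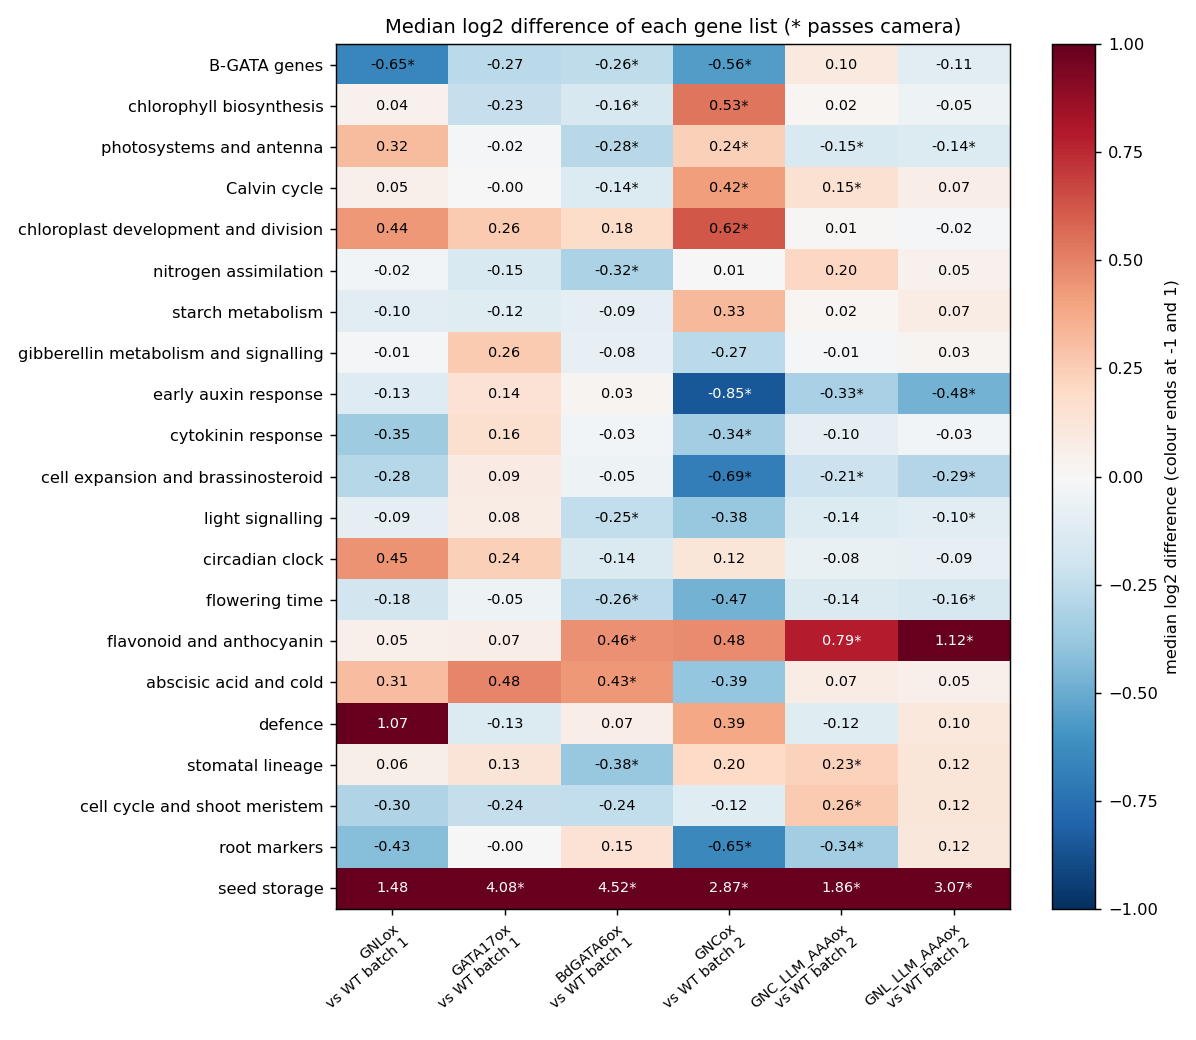
Median log2 difference of 21 gene lists (vertical) in 6 comparisons with wild type (horizontal), colours from -1 to 1, with * where the list passed at adjusted p under 0.05 with the preset correlation, none with an estimated correlation. Chlorophyll biosynthesis stands at 0.53 in GNCox and flavonoid genes at 1.12 in GNL_LLM_AAAox, and the photosystem medians of 0.32 in GNLox and 0.24 in GNCox became -0.09 in both after quantile normalization.

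**Figure D4:**
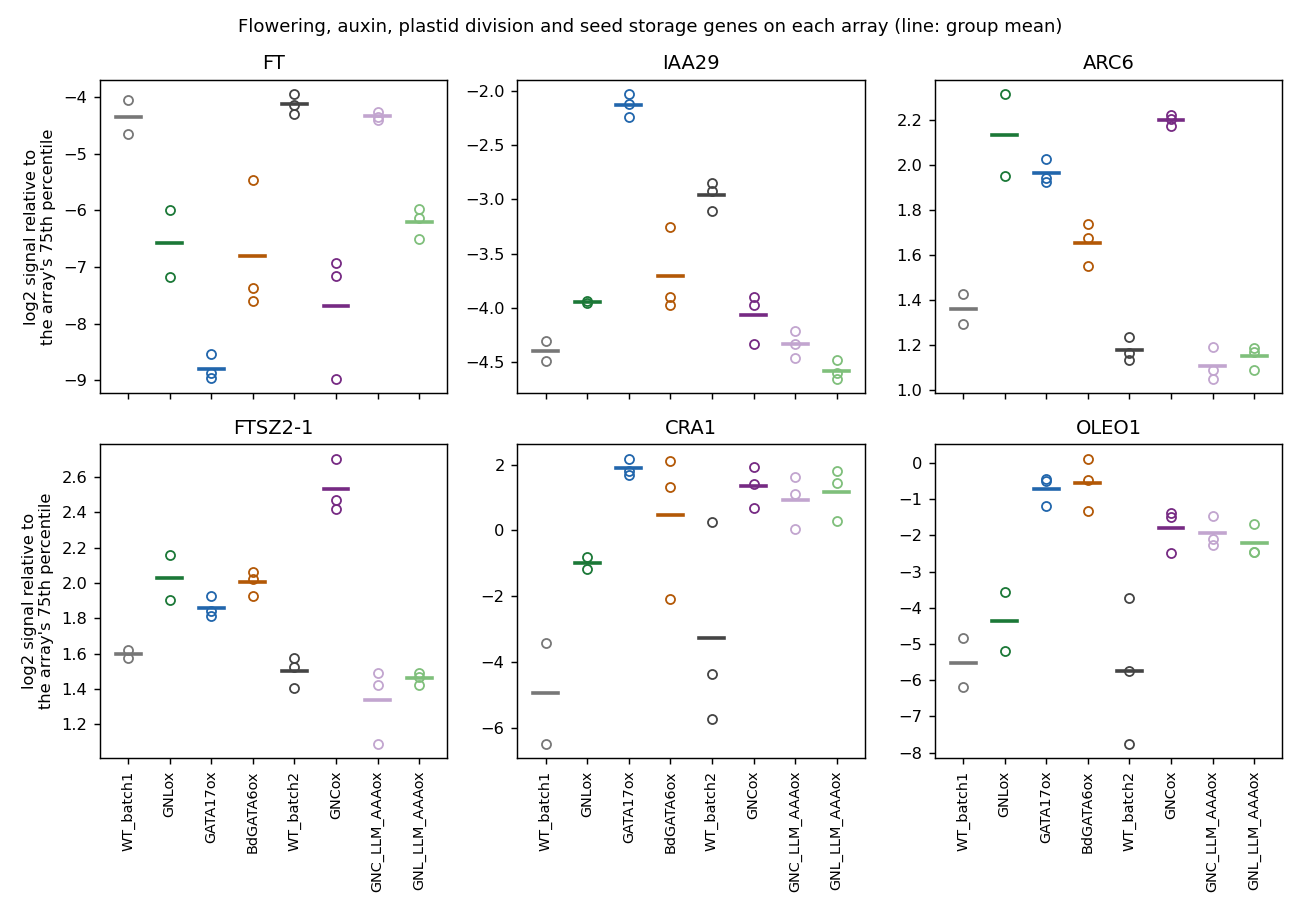
Signal of FT, IAA29, ARC6, FTSZ2-1, CRA1 and OLEO1 on each of 22 arrays by group, log2 relative to the array's 75th percentile. ARC6 differs from wild type by 1.02 in GNCox and 0.77 in GNLox.

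GNC_LLM_AAAox was compared with the same wild type (n = 3 and 3) to see what remains without the LLM motif. Flavonoid and anthocyanin genes rose for 7 of 15 and fell for 1 (8 and 1 over the list alone), median 0.79 (slide-blocked 0.90). The flavonoid list passed at adjusted p = 1.06e-05 (0.14 with an estimated correlation). UF3GT (1.44 ± 0.21, adjusted p = 0.000397) and 5MAT (1.44 ± 0.15, adjusted p = 2.12e-05), which decorate anthocyanins, rose. Early auxin response genes fell for 10 of 29 and rose for 2 (16 and 2 over the list alone), median -0.33 (slide-blocked -0.51). The auxin list passed at adjusted p = 1.06e-05 (0.14 with an estimated correlation). IAA29 fell most (-1.38 ± 0.16, adjusted p = 3.12e-05), and SAUR9 fell (-1.01 ± 0.19, adjusted p = 0.00243). Root markers fell for 7 of 23 and rose for 0 (8 and 0 over the list alone), median -0.34 (slide-blocked -0.67). The root marker list passed at adjusted p = 0.000153 (0.241 with an estimated correlation). FRO2, a ferric reductase, fell (-1.77 ± 0.32). Cell expansion genes fell for 6 of 18 and rose for 0 (7 and 0 over the list alone), median -0.21 (slide-blocked -0.45). The cell expansion list passed at adjusted p = 0.00121 (0.14 with an estimated correlation). EXPA8, an expansin, was at -0.79, and its call ended when slide-blocked (-1.13, adjusted p = 0.057). Seed storage transcripts rose for 4 of 10 and fell for 0 (7 and 0 over the list alone), median 1.86 (slide-blocked 2.50). The seed storage list passed at adjusted p = 3.95e-05 (0.14 with an estimated correlation). OLEO1 (3.81 ± 0.75, adjusted p = 0.00301) and OLEO2 (3.02 ± 0.60, adjusted p = 0.00326) were higher, at 2.84 and 1.98 and not called when slide-blocked.

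Calvin cycle genes in GNC_LLM_AAAox rose for 5 of 15 and fell for 0 (6 and 0 over the list alone), median 0.15 (slide-blocked 0.13). The Calvin cycle list passed at adjusted p = 0.00382 (0.241 with an estimated correlation). SBPASE rose (0.39 ± 0.08, adjusted p = 0.00297), slide-blocked 0.40 and not called. Stomatal lineage genes rose for 3 of 11 and fell for 0 (4 and 0 over the list alone), median 0.23 (slide-blocked 0.22). The stomatal list passed at adjusted p = 0.00105 (0.186 with an estimated correlation). POLAR rose (0.58 ± 0.10), slide-blocked 0.39 and not called. Cell cycle genes rose for 1 of 11 and fell for 0 (4 and 0 over the list alone), median 0.26 (slide-blocked 0.21). The cell cycle list passed at adjusted p = 0.0013 (0.14 with an estimated correlation). CDC20 was the single call (0.35), not called slide-blocked (0.25) or without WT_batch2 replicate A (0.35, adjusted p = 0.055). Photosystem and antenna genes fell for 3 of 32 and rose for 0 (5 and 1 over the list alone), median -0.15 (slide-blocked -0.37). The photosystem list passed at adjusted p = 0.000472 (0.364 with an estimated correlation). LHCB2.1 fell (-0.57), a call that ended without any 1 of 5 arrays, as without WT_batch2 replicate A (-0.45, adjusted p = 0.19). The B-GATA median of 0.10 was -0.01 when normexp-corrected.

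Among single genes in GNC_LLM_AAAox, CYP82C4, of iron-related coumarin synthesis (-4.08 ± 0.60, adjusted p = 0.000345), and CWINV5 (-3.90 ± 0.76, adjusted p = 0.00296) fell. CYP71B22 (-3.81 ± 0.37, adjusted p = 9.9e-06, at least 9.4-fold) fell as well. PR2, a pathogenesis-related glucanase, fell (-4.68 ± 1.39, adjusted p = 0.0388), a call that ended without WT_batch2 replicate C (-2.99, adjusted p = 0.20). ATPXG2 rose (4.17 ± 0.67, adjusted p = 0.000683, at least 5.59-fold), slide-blocked 3.18 and not called. The total of 3100 calls was 1724 without WT_batch2 replicate A, with 41.7% higher and 30.4% when slide-blocked.

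GNL_LLM_AAAox asks the same of GNL (n = 3 and 3). SESA5 (8.10 ± 1.3, adjusted p = 0.000468, at least 63.9-fold) and ATPXG2 (4.60 ± 0.67, adjusted p = 0.000208, at least 7.50-fold) rose, at 6.88 and 3.80 and not called when slide-blocked. ICL rose (4.24 ± 0.89, adjusted p = 0.00347), slide-blocked 3.62 and not called. HAK5, a root potassium transporter, fell most (-4.92 ± 0.32, adjusted p = 1.51e-07). MEE39 (-3.51 ± 0.32, adjusted p = 2.97e-06, at least 2.53-fold) and the peroxidase PRXCA (-2.93 ± 0.21, adjusted p = 4.9e-07) fell. Early auxin response genes fell for 19 of 29 and rose for 1 (20 and 1 over the list alone), median -0.48 (slide-blocked -1.01). The auxin list passed at adjusted p = 1.44e-11 (adjusted p = 0.0624 with an estimated correlation). IAA29 (-1.62 ± 0.16, adjusted p = 5.25e-06) and LBD29, of lateral roots (-1.90 ± 0.33, adjusted p = 0.000797), fell. Flavonoid genes rose for 11 of 15 and fell for 1 (14 and 1 over the list alone), median 1.12 (slide-blocked 1.07). The flavonoid list passed at adjusted p = 6.49e-08 (adjusted p = 0.134 with an estimated correlation). 5MAT (1.73 ± 0.15, adjusted p = 2.8e-06) and UF3GT (1.61 ± 0.21, adjusted p = 0.000104) rose.

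Cell expansion genes in GNL_LLM_AAAox fell for 7 of 18 and rose for 0 (8 and 1 over the list alone), median -0.29 (slide-blocked -0.61). The cell expansion list passed at adjusted p = 0.0025 (adjusted p = 0.134 with an estimated correlation). EXPA8 fell most (-2.08 ± 0.17, adjusted p = 1.21e-06). Seed storage transcripts rose for 9 of 10 and fell for 0 (9 and 0 over the list alone), median 3.07 (slide-blocked 3.04). The seed storage list passed at adjusted p = 2.44e-05 (adjusted p = 0.134 with an estimated correlation). OLEO1 rose (3.53 ± 0.75, adjusted p = 0.00367), slide-blocked 2.72 and not called. Flowering genes fell for 8 of 23 and rose for 1 (8 and 1 over the list alone), median -0.16 (slide-blocked -0.20). The flowering list passed at adjusted p = 0.00454 (adjusted p = 0.134 with an estimated correlation). FT (-2.07 ± 0.52, adjusted p = 0.0116) and SPL3, a promoter of flowering (-1.54 ± 0.15, adjusted p = 4.53e-06), fell. Light signalling genes fell for 7 of 19 and rose for 2 (7 and 2 over the list alone), median -0.10 (slide-blocked -0.12). The light signalling list passed at adjusted p = 0.0245 (adjusted p = 0.349 with an estimated correlation). PAR1 (-1.03 ± 0.12) and HFR1 (-1.26 ± 0.23) fell. Photosystem genes fell for 4 of 32 and rose for 1 (4 and 1 over the list alone), median -0.14 (slide-blocked -0.34). The photosystem list passed at adjusted p = 0.00454 (adjusted p = 0.797 with an estimated correlation). B-GATA genes had a median of -0.11 and a mean of 0.38, and defence genes a median of 0.10 with a test toward lower. The 4862 calls were 2894 without WT_batch2 replicate A. Of them 49.0% were higher (slide-blocked 27.6%), and of the 2-fold calls 49.9% (15.9%).

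GNC_LLM_AAAox against GNCox compares separate lines with and without the LLM motif within 1 batch (n = 3 and 3, slide-blocked 2 and 2). Chlorophyll biosynthesis genes fell for 19 of 23 and rose for 0 (19 and 0 over the list alone), median -0.53 (slide-blocked -0.51). The chlorophyll list passed at adjusted p = 6.29e-05 (0.395 with an estimated correlation). CHLD (-0.85 ± 0.09) and CHLI1 (-0.74 ± 0.07, adjusted p = 5.19e-07) were among them. Genes of chloroplast development and division fell for 11 of 16 and rose for 1 (11 and 1 over the list alone), median -0.60 (slide-blocked -0.53). The chloroplast list passed at adjusted p = 0.00104 (0.395 with an estimated correlation). ARC6 (-1.09 ± 0.08, adjusted p = 3.29e-08) and FTSZ2-1 (-1.19 ± 0.10, adjusted p = 1.09e-07) fell. Photosystem genes fell for 26 of 32 and rose for 0 (28 and 0 over the list alone), median -0.40 (slide-blocked -0.47). The photosystem list passed at adjusted p = 6.29e-05 (0.479 with an estimated correlation). Calvin cycle genes fell for 10 of 15 and rose for 0 (12 and 0 over the list alone), median -0.34 (slide-blocked -0.40). The Calvin cycle list passed at adjusted p = 0.00518 (0.395 with an estimated correlation). Quantile normalization left photosystem and Calvin cycle medians of -0.06 (adjusted p = 0.414) and -0.02 (adjusted p = 0.637). B-GATA genes, GNC included, rose for 9 of 11 and fell for 0 (9 and 0 over the list alone), median 0.70 (slide-blocked 0.64). The B-GATA list passed at adjusted p = 0.000541 (0.395 with an estimated correlation). GNL (1.66 ± 0.13, adjusted p = 4.8e-08), GATA16 (1.45 ± 0.16) and GATA15 (1.2 ± 0.12) rose most. Early auxin response genes rose for 17 of 29 and fell for 2 (17 and 2 over the list alone), median 0.39 (slide-blocked 0.26). The auxin list passed at adjusted p = 0.0124 (0.479 with an estimated correlation). IAA3 rose (0.79 ± 0.10), while SAUR9 (1.1 ± 0.19, adjusted p = 0.000151) was -0.002 as the mean of its probes.

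FT rose in GNC_LLM_AAAox over GNCox (3.34 ± 0.52, adjusted p = 5.09e-05, at least 5.73-fold), as did FUL (2.17 ± 0.27) and VSP2 (2.84 ± 0.36). ASN1, an asparagine synthetase, rose (2.12 ± 0.45). ELIP2 fell (-2.16 ± 0.21, adjusted p = 5.39e-07). The largest rises were CSLA01 (4.39 ± 1.16, adjusted p = 0.00427, at least 9.32-fold), MES18 (3.82 ± 0.68, adjusted p = 0.000178) and the zinc finger factor ZFP10 (3.73 ± 0.32, adjusted p = 1.32e-07, at least 6.09-fold). The largest falls were PNP-A (-5.67 ± 1.36, adjusted p = 0.00216), ARCK1, a receptor kinase (-5.57 ± 0.48, adjusted p = 1.41e-07), and MPK10 (-5.54 ± 0.18, adjusted p = 5.84e-12). Here 14858 genes changed, 2450 at least 2-fold (slide-blocked 12738 and 1965). Of the 2-fold calls 53.3% were higher, 43.0% normexp-corrected.

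GNL_LLM_AAAox against GNLox is a difference of differences, so changes are relative to GNLox (n = 3, 3, 2 and 2). B-GATA genes, the transgene GNL included, rose for 8 of 11 and fell for 0 (9 and 0 over the list alone), median 0.83 (slide-blocked 0.72). The B-GATA list passed at adjusted p = 1.27e-05 (adjusted p = 0.28 with an estimated correlation). GNC (2.57 ± 0.25) and GATA16 (2.99 ± 0.26) rose over GNLox but not over wild type (-0.48 and -0.12). GATA16 was at 1.41 with the background level for GNLox and -0.03 normexp-corrected. Flavonoid genes rose for 8 of 15 and fell for 0 (8 and 0 over the list alone), median 0.64 (slide-blocked 0.67). The flavonoid list passed at adjusted p = 0.0011 (adjusted p = 0.558 with an estimated correlation). Photosystem genes fell for 15 of 32 and rose for 0 (20 and 1 over the list alone), median -0.46 (slide-blocked -0.72). The photosystem list passed at adjusted p = 0.00228 (adjusted p = 0.643 with an estimated correlation). After quantile normalization the photosystem median was -0.07 (adjusted p = 0.98). Chloroplast development genes fell for 7 of 16 and rose for 0 (8 and 0 over the list alone), median -0.45 (slide-blocked -0.15). The chloroplast list passed at adjusted p = 0.0107 (adjusted p = 0.558 with an estimated correlation). Defence genes fell for 9 of 19 and rose for 1 (9 and 1 over the list alone), median -1.14 (slide-blocked -0.60). The defence list passed at adjusted p = 0.0428 (adjusted p = 0.558 with an estimated correlation). Cell cycle genes rose for 6 of 11 and fell for 1 (7 and 1 over the list alone), median 0.43 (slide-blocked 0.42). The cell cycle list passed at adjusted p = 0.0451 (adjusted p = 0.558 with an estimated correlation). Root markers rose for 8 of 23 and fell for 0 (8 and 0 over the list alone), median 0.42 (slide-blocked -0.02). The root marker list passed at adjusted p = 0.0107 (adjusted p = 0.558 with an estimated correlation). PUM7 fell (-9.68 ± 0.77, adjusted p = 1.04e-06, -7.52 with the background level). JAL31 (4.88 ± 0.51, adjusted p = 1.06e-05, 3.77 with that level) and NDB3, an NADH dehydrogenase (4.67 ± 0.71, adjusted p = 0.000199), rose. TPS04 (-10.97 ± 2.21, adjusted p = 0.00161), NATA1 (-10.08 ± 2.56, adjusted p = 0.00699) and CYP71A12 (4.65 ± 1.13, adjusted p = 0.00535) were not called when slide-blocked (-5.88, -5.03 and 3.28), and TPS04 was at -6.92 with the background level. Of 9748 calls 43.7% were higher (28.3% normexp-corrected), and of the 2785 2-fold calls 57.4% (38.1%, slide-blocked 37.4%). Without WT_batch1 replicate 1 there were 6339 calls, and slide-blocked 5346.

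Of the 3071 genes changed at least 2-fold in GNCox, 750 (24.4%) were called in the same direction in GNC_LLM_AAAox, 112 in the opposite direction and 2209 not at all. The test between the lines called 2469 (80.4%) smaller in GNC_LLM_AAAox. Their median change was 1.32 in GNCox and 0.22 (quartiles -0.05 and 0.68) in GNC_LLM_AAAox, in the direction of GNCox. Choosing genes by large changes may add to this drop, also for GNL. FT was -3.55 in GNCox and -0.21 in GNC_LLM_AAAox. For GNL the numbers were 624 of 3001 (20.8%, slide-blocked 12%), 135 and 2242, with 2069 (68.9%) smaller. Medians were 1.45 in GNLox and 0.17 (quartiles -0.10 and 0.57) in GNL_LLM_AAAox. FT kept its fall, -2.22 in GNLox and -2.07 in GNL_LLM_AAAox. The mutation effect on FT differed between GNC and GNL by 3.19, or 2.37 with the background level for GNCox. In all 4814 genes had such a difference. Of the 725 genes changed at least 2-fold in GNC_LLM_AAAox 496 were called the same way in GNCox, 70 the opposite way and 159 not. Of the 999 in GNL_LLM_AAAox it was 410, 76 and 513 in GNLox.

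**Figure D5:**
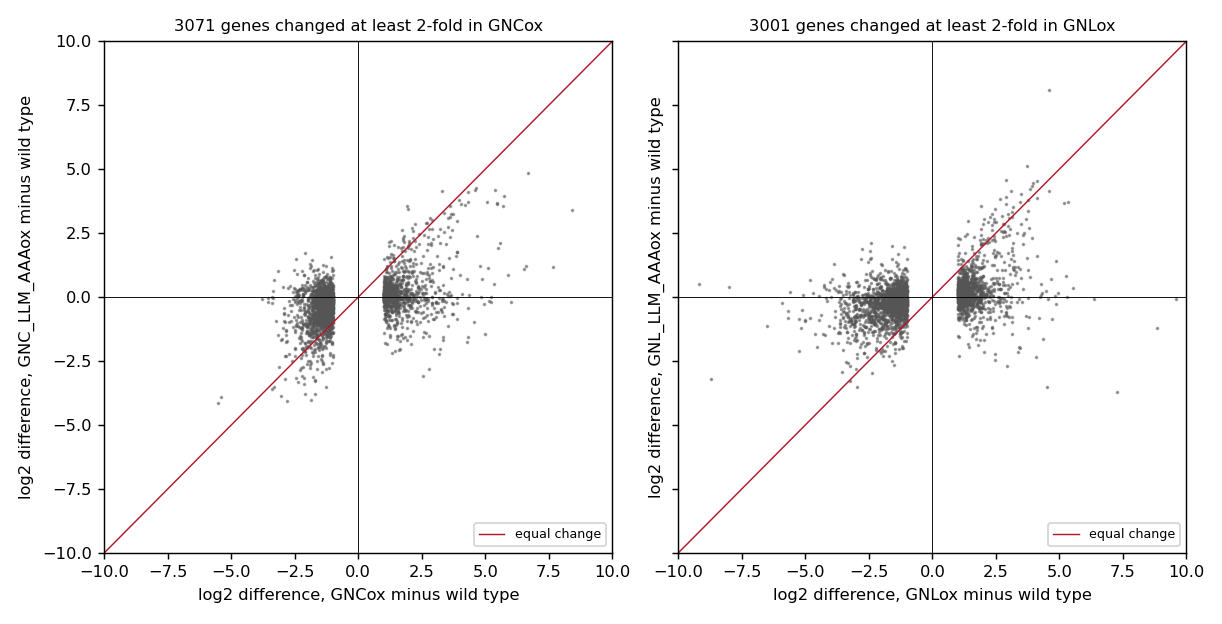
Log2 difference from wild type in GNCox (horizontal) against GNC_LLM_AAAox (vertical) for 3071 genes changed at least 2-fold in GNCox, and in GNLox against GNL_LLM_AAAox for 3001 genes, with the line of equal change. Median changes were 1.32 and 0.22 for GNC, 1.45 and 0.17 for GNL.

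GATA17ox was compared with GNLox within batch 1 (n = 3 and 2), with GATA17ox named as higher or lower. Auxin response genes were higher for 13 of 29 and were lower for 1 (16 and 1 over the list alone), median 0.44 (slide-blocked 0.47). The auxin list passed at adjusted p = 9.54e-05 (0.333 with an estimated correlation). Root markers were higher for 12 of 23 and were lower for 0 (13 and 0 over the list alone), median 0.57 (slide-blocked 0.79). The root marker list passed at adjusted p = 0.00381 (0.435 with an estimated correlation). Gibberellin genes were higher for 10 of 24 and were lower for 0 (11 and 0 over the list alone), median 0.28 (slide-blocked 0.26). The gibberellin list passed at adjusted p = 0.0242 (0.204 with an estimated correlation). Cytokinin genes were higher for 8 of 19 and were lower for 2 (8 and 2 over the list alone), median 0.33 (slide-blocked 0.16). The cytokinin list passed at adjusted p = 0.0364 (0.432 with an estimated correlation). Cell expansion genes were higher for 10 of 18 and were lower for 2 (11 and 3 over the list alone), median 0.44 (slide-blocked 0.46). The cell expansion list passed at adjusted p = 0.0445 (0.432 with an estimated correlation). Seed storage transcripts were higher for 5 of 10 and were lower for 0 (8 and 0 over the list alone), median 2.82 (slide-blocked 2.74). The seed storage list passed at adjusted p = 0.00965 (0.432 with an estimated correlation). Defence genes were lower for 12 of 19 and were higher for 1 (13 and 1 over the list alone), median -0.77 (slide-blocked -1.03). The defence list passed at adjusted p = 3.35e-05 (0.204 with an estimated correlation). The defensin PDF1.2 was lower (-6.55 ± 1.31, adjusted p = 0.000989). Photosystem genes were lower for 17 of 32 and were higher for 0 (18 and 0 over the list alone), median -0.34 (slide-blocked -0.21). The photosystem list passed at adjusted p = 2.01e-05 (0.432 with an estimated correlation). Chlorophyll genes were lower for 8 of 23 and were higher for 2 (10 and 3 over the list alone), median -0.22 (slide-blocked -0.26). The chlorophyll list passed at adjusted p = 0.0187 (0.439 with an estimated correlation). Chlorophyll genes did not pass after quantile normalization (adjusted p = 0.381).

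PUM7 (-9.33 ± 0.55, adjusted p = 1.19e-08, at least 152-fold) and NATA1 (-7.80 ± 1.81, adjusted p = 0.00303) were lower in GATA17ox than in GNLox. WAKL1, a wall-associated kinase (4.46 ± 0.32, adjusted p = 7.84e-08, at least 4.94-fold), GATA29 (4.41 ± 0.79, adjusted p = 0.00041, at least 5.87-fold) and HAP13 (4.85 ± 1.45, adjusted p = 0.0153) were higher. Of 10201 calls 1849 were at least 2-fold (slide-blocked 8982 and 2060), 70.9% of these higher (57.9% after quantile normalization).

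BdGATA6ox against GNLox (n = 3 and 2) uses the same GNLox arrays, so its lists are not independent of those of GATA17ox against GNLox. Photosystem and antenna genes were lower for 25 of 32 and were higher for 2 (26 and 2 over the list alone), median -0.62 (slide-blocked -0.34). The photosystem list passed at adjusted p = 2.26e-07 (adjusted p = 0.383 with an estimated correlation). After quantile normalization the photosystem median was -0.02 and the test in the other direction (adjusted p = 0.900). Root markers were higher for 12 of 23 and were lower for 2 (12 and 2 over the list alone), median 0.65 (slide-blocked 0.78). The root marker list passed at adjusted p = 0.00394 (adjusted p = 0.383 with an estimated correlation). Auxin response genes were higher for 12 of 29 and were lower for 2 (12 and 2 over the list alone), median 0.26 (slide-blocked 0.25). The auxin list passed at adjusted p = 0.0073 (adjusted p = 0.383 with an estimated correlation). B-GATA genes were higher for 7 of 11 and were lower for 1 (9 and 2 over the list alone), median 0.46 (slide-blocked 0.29). The B-GATA list passed at adjusted p = 0.00733 (adjusted p = 0.383 with an estimated correlation). The B-GATA median was -0.05 when normexp-corrected. Defence genes were lower for 13 of 19 and were higher for 2 (13 and 2 over the list alone), median -1.01 (slide-blocked -0.36). The defence list passed at adjusted p = 0.00733 (adjusted p = 0.383 with an estimated correlation). Stomatal lineage genes were lower for 7 of 11 and were higher for 0 (8 and 0 over the list alone), median -0.42 (slide-blocked -0.48). The stomatal list passed at adjusted p = 0.00733 (adjusted p = 0.383 with an estimated correlation). Clock genes were lower for 7 of 15 and were higher for 1 (7 and 1 over the list alone), median -0.41 (slide-blocked -0.29). The clock list passed at adjusted p = 0.0361 (adjusted p = 0.383 with an estimated correlation). Chlorophyll genes were lower for 12 of 23 and were higher for 2 (12 and 2 over the list alone), median -0.20 (slide-blocked -0.38). The chlorophyll list passed at adjusted p = 0.0216 (adjusted p = 0.457 with an estimated correlation).

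PUM7 (-10.28 ± 0.55, adjusted p = 1.13e-08, at least 285-fold) and LAS1, a triterpene synthase (-4.66 ± 0.35, adjusted p = 3.22e-07), were lower in BdGATA6ox than in GNLox. TPS-CIN (4.93 ± 0.23, adjusted p = 2.26e-09), LTP4 (4.85 ± 0.58, adjusted p = 1.72e-05), GEX1 (4.76 ± 0.45, adjusted p = 2.08e-06, at least 11.9-fold) and TPS12 (4.71 ± 0.33, adjusted p = 1.91e-07, at least 9.94-fold) were higher. Of 12146 calls 44.4% were higher, 21.7% normexp-corrected, with 7290 calls without GNLox replicate 1 and 3442 slide-blocked (55.1% higher). Of the 2436 2-fold calls 66.9% were higher, against 24.2% normexp-corrected and 56.7% after quantile normalization.

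BdGATA6ox was compared with GATA17ox (n = 3 and 3). Stomatal lineage genes were lower for 9 of 11 and were higher for 0 (9 and 0 over the list alone), median -0.55 (slide-blocked -0.63). As a list stomatal genes passed at adjusted p = 0.0181 (adjusted p = 0.753 with an estimated correlation). No other list passed. LTP4 (5.01 ± 0.51, adjusted p = 1.03e-06), GEX1 (4.49 ± 0.40, adjusted p = 2.44e-07, at least 10.14-fold) and MRD1 (4.38 ± 0.25, adjusted p = 4.02e-09) were higher. LCR67 (-6.92 ± 0.66, adjusted p = 5.13e-07) and CYP71A18 (-4.87 ± 0.67, adjusted p = 1.88e-05, at least 16.7-fold) were lower. Photosystem genes had a median of -0.23, and 0.18 after quantile normalization, where the list passed toward higher (adjusted p = 0.0170). Of 15574 calls 43.4% were higher (27.4% normexp-corrected), and of 3231 2-fold calls 45.5% (16.5%, slide-blocked 34.4%). Slide-blocked there were 12688 and 3076.

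GNCox against GNLox compares the effect of each paralogue over its own wild type (n = 3, 3, 2 and 2). Chlorophyll biosynthesis genes were higher for 12 of 23 and were lower for 1 (15 and 1 over the list alone), median 0.46 (slide-blocked 0.64). The chlorophyll list passed at adjusted p = 4.42e-07 (adjusted p = 0.243 with an estimated correlation). Calvin cycle genes were higher for 9 of 15 and were lower for 0 (9 and 0 over the list alone), median 0.59 (slide-blocked 0.59). The Calvin cycle list passed at adjusted p = 0.000193 (adjusted p = 0.243 with an estimated correlation). Starch genes were higher for 6 of 15 and were lower for 0 (6 and 1 over the list alone), median 0.30 (slide-blocked 0.47). The starch list passed at adjusted p = 0.00102 (adjusted p = 0.387 with an estimated correlation). Chloroplast development genes were higher for 5 of 16 and were lower for 2 (6 and 2 over the list alone), median 0.25 (slide-blocked 0.39). The chloroplast list passed at adjusted p = 0.0257 (adjusted p = 0.387 with an estimated correlation). Cell cycle genes were higher for 3 of 11 and were lower for 1 (4 and 1 over the list alone), median 0.31 (slide-blocked 0.43). The cell cycle list passed at adjusted p = 0.0376 (adjusted p = 0.387 with an estimated correlation). Auxin response genes were lower for 11 of 29 and were higher for 1 (11 and 1 over the list alone), median -0.33 (slide-blocked -0.52). The auxin list passed at adjusted p = 0.0144 (adjusted p = 0.387 with an estimated correlation). Abscisic acid and cold genes were lower for 6 of 17 and were higher for 0 (6 and 0 over the list alone), median -0.75 (slide-blocked -1.02). The abscisic acid list passed at adjusted p = 0.00905 (adjusted p = 0.387 with an estimated correlation). Defence genes were lower for 6 of 19 and were higher for 0 (6 and 0 over the list alone), median -0.68 (slide-blocked -0.72). The defence list passed at adjusted p = 0.0257 (adjusted p = 0.387 with an estimated correlation).

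NAC085 (5.0 ± 0.52, adjusted p = 5.85e-05, 1.69 with the background level) and NDB3 (3.65 ± 0.71, adjusted p = 0.00351) were higher under GNC than GNL. So was GNC (4.18 ± 0.25, adjusted p = 8.01e-08), at 1.13 in GNCox and -3.05 in GNLox, with 1.32 by probe A_84_P212728, which fell in both. PUM7 (-9.41 ± 0.77, adjusted p = 3.68e-06), the receptor-like protein RLP40 (-6.47 ± 1.33, adjusted p = 0.00476), both at less with that level (-7.31 and -5.51), LAS1 (-4.83 ± 0.50, adjusted p = 5.85e-05) and JAL23 (-4.22 ± 0.56, adjusted p = 0.000388) were lower. Of 5291 calls 43.6% were higher, 29.0% normexp-corrected, and of the 1215 2-fold calls 46.5% (35.2%, slide-blocked 36.1%). Without GNLox replicate 1 the counts were 2592 and 743, without GNLox replicate 2 they were 7773 and 2164, and slide-blocked 8974 and 2985.

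GNLox and GNCox share no controls. Among their 2-fold genes 476 were higher in both (51.9 for independent lists), 948 lower in both (123) and 15 opposite (160). MRD1 was among the higher (5.29 and 5.34) and CWINV5 among the lower (-5.01 and -5.42), and log2 differences correlated at 0.62 (rank correlation 0.62). GATA17ox and GNCox shared 451 higher and 500 lower (90.3 and 100), LCR67 among the higher (9.34 and 5.49). BdGATA6ox and GNCox shared 451 and 214 (46.8 and 44.4), ATPXG2 among the higher (6.99 and 5.38). Opposite were 76 (209) and 33 (104), and the correlations 0.43 and 0.50. GNLox and GNL_LLM_AAAox shared 156 and 160 (22.3 and 32.2), with 51 opposite (54.6), at 0.27.

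Other pairs share controls. GNLox and GATA17ox had 793 higher and 798 lower in both (95.8 and 92.8), and GNLox and BdGATA6ox 481 and 340 (49.6 and 41.2). GATA17ox and BdGATA6ox shared 560 and 279 (86.3 and 33.5), GNCox and GNC_LLM_AAAox 106 and 286 (9.25 and 35.2), and both LLM-mutated lines 130 and 176 (3.98 and 9.21). Opposite in that order were 25 (202), 19 (100), 31 (108), 52 (36.6) and 7 (13.2), more than for independent lists only between GNCox and GNC_LLM_AAAox. In that order their correlations were 0.68, 0.57, 0.57, 0.37 and 0.63, against 0.55, 0.55, 0.60, 0.50 and 0.50 in 100 simulations with shared controls and no effect. The covariances were 0.430, 0.316, 0.324, 0.114 and 0.130, against simulated values of 0.0390, 0.0391, 0.0390, 0.0259 and 0.0259. Part of the excess overlap in these pairs may come from the shared controls, which are too few to split between comparisons.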

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

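All tests in this part but the regroupings were chosen only after the result or values close to it were seen, and the genes of the mixing test were redefined after a first look at genes raised at least 8-fold in GNL_LLM_AAAox.

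The effect of the LLM mutation (mutated minus unmutated line) differed between GNC and GNL for 4814 genes, 1711 of them at least 2-fold. Among 379 list members tested 101 differed, 55 higher for GNC and 46 higher for GNL. GNC minus GNL was -3.08 for SESA2, -2.14 for GNC, -1.87 for ELIP2 and -1.75 for FLC, and 3.02 for ASN1, 3.19 for FT (2.37 with the background level for GNCox, where no array was above it), 3.597 for VSP2 and 3.75 for VSP1. These genes were chosen after their values were seen. The GNL side crosses the batches, so line, batch and slide stand together in this difference.

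GNL transcript was higher in GNC_LLM_AAAox than in wild type (1.69) and not in GNCox. Cross-hybridisation of the GNC transgene's transcript to the GNL probe would raise it in GNCox too. There GNL was 0.031 (SE 0.126) against 0.843 needed, which speaks against cross-hybridisation. A fall of GNL's own transcript there, as for GATA15 (-0.98) and GATA16 (-1.36), could hide it, so it is not excluded. RNA of GNL_LLM_AAAox mixed in at 6.58% would raise 43 further genes by a median of 0.35, and they were at 0.94, with a median of observed minus predicted of 0.55 (quartiles 0.01 and 1.26), so mixing could neither be shown nor excluded. Induction of the GNL gene itself by the mutated GNC protein remains open, untested.

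Genes changed at least 2-fold in GNCox changed less in GNC_LLM_AAAox. A lower transgene transcript could be the cause. The GNC probe raised in both lines was higher in the mutated line (0.42, SE 0.158, adjusted p = 0.0320), which speaks against it. Probe positions are not given and the probe reads endogenous GNC as well, and the other probe, below wild type in both lines, was higher by 0.45 (SE 0.187, adjusted p = 0.0552), so this remains open. Slide differences are excluded, since within the slide holding both lines 2140 of 2947 such genes (72.6%) were still called smaller. The choice of genes, a loss of function through the LLM motif and less protein remain open.

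Seed storage transcripts had a higher median in 6 overexpression lines and passed as a list in 5, in 0 with an estimated correlation (adjusted p = 0.775 in GATA17ox) and in 2 with slide as a fixed block. In GNLox 3 of 10 rose and 0 fell (0 over the list alone), with a median of 1.48 and adjusted p = 0.227. If 1 source of seed RNA of fixed composition were the only cause, BdGATA6ox and GATA17ox would differ in 1 direction. Yet OLEO2 was higher in BdGATA6ox (1.90, adjusted p = 0.0127) and 4 others lower, down to SESA4 (-3.34, adjusted p = 0.000125). This speaks against it alone there. No single array sets the median rise, as the lowest median with 1 array left out was 1.21 in GNLox, 3.94 in GATA17ox, 3.03 in BdGATA6ox, 2.69 in GNCox, 1.73 in GNC_LLM_AAAox and 2.62 in GNL_LLM_AAAox. Single genes do stand apart on single arrays. CRA1 (0.26) and CRC (-0.87) in WT_batch2 replicate B were near the levels of the lines, and CRC in BdGATA6ox replicate 3 was -6.92 against -0.08 and -0.45. Seed RNA in part, delayed development or a direct effect remains open, untested.

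Regrouping the 6 arrays of a comparison allows 10 splits, too few for a test, as the share of splits as high as the real 1 is never under 10%. The real grouping was the highest in each of the 5 comparisons (1 of 10), and the highest other split gave 2 called genes for GNCox, 1 for GNC_LLM_AAAox, 1 for GNL_LLM_AAAox, 1 for GNC_LLM_AAAox against GNCox and 8 for BdGATA6ox against GATA17ox.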

How the results depend on the processing

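The normexp-corrected values, slide as a fixed block and within-slide tests were added only after the data were seen, the others planned. Of the named genes' values the largest shares kept their call with eBayes trend and robust (581 of 585), probes above background on every array (426 of 430), no filter (572 of 585) and quantile normalization (562). Then came a replicate block (539 of 563), the mean of probes (556 of 585), the shared slide alone (239 of 254), normexp without spots under a bright background (533 of 585), slide as a random block (510 of 563), arrays of the same batch (491 of 544) and slide as a fixed block (422 of 563). The cause of the changes was not tested unless stated.

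Arrays of the same batch only left 8349 calls for GNLox, 4207 for BdGATA6ox, 5918 for GATA17ox against GNLox and 6481 for BdGATA6ox against GNLox, and 4866 for GNC_LLM_AAAox and 7861 for GNL_LLM_AAAox. With slide as a random block (correlation 0.352) BdGATA6ox had 4294 (1147 at least 2-fold), GNC_LLM_AAAox 2023, GNL_LLM_AAAox 2097 and BdGATA6ox against GNLox 7900. With slide as a fixed block BdGATA6ox had 3477, GNL_LLM_AAAox 1891, GNL_LLM_AAAox against GNLox 5346, BdGATA6ox against GNLox 3442 (1587 at least 2-fold) and GNCox against GNLox 8974 (2985). The share of GNLox calls kept in GNL_LLM_AAAox was 13.3% with slide as a random and 12% as a fixed block.

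Normexp without spots under a bright background left 2-fold counts of 1658 for GNLox, 2329 for GATA17ox, 894 for BdGATA6ox, 1713 for GNCox, 378 for GNC_LLM_AAAox, 420 for GNL_LLM_AAAox, 1445 for GNC_LLM_AAAox against GNCox, 1633 for GNL_LLM_AAAox against GNLox and 756 for GATA17ox against GNLox. This setting changes the signal column, the background step, the spots and an offset at once, so the cause is open. Probes above background on every array left 959 for BdGATA6ox, 439 for GNC_LLM_AAAox, 551 for GNL_LLM_AAAox and 1515 for BdGATA6ox against GNLox, and no filter gave 2851 for BdGATA6ox.

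Lists passing were 3 in GNLox, 2 in GATA17ox and 2 in BdGATA6ox against GATA17ox after quantile normalization, 3 in GATA17ox with the mean of probes, and 0 in all 12 comparisons with an estimated correlation. With slide as a fixed block they were 0 in GATA17ox, 6 in BdGATA6ox, 6 in GNCox, 4 in GNL_LLM_AAAox against GNLox and 5 in GNCox against GNLox. The directional fry test passed 13 in GNLox, 12 in GATA17ox, 17 in GNCox, 15 in GNC_LLM_AAAox, 15 in GNC_LLM_AAAox against GNCox, 17 in BdGATA6ox against GNLox and 12 in BdGATA6ox against GATA17ox. The mixed fry test passed 20 in GNLox, 21 in GATA17ox, 21 in BdGATA6ox, 21 in GNCox, 19 in GNC_LLM_AAAox, 16 in GNL_LLM_AAAox, 20 in both mutated against unmutated comparisons, 21 in the 3 other comparisons of batch 1 and 19 in GNCox against GNLox.

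Directions turned for few values. The photosystem list passed toward the other side after quantile normalization in GNLox (adjusted p = 0.0439) and BdGATA6ox against GATA17ox (0.0170), and turned without passing in GNCox (0.186) and BdGATA6ox against GNLox (0.900). The Calvin cycle list did so in GNLox (0.0439) and BdGATA6ox against GNLox (0.0210), and RBCS1A in GATA17ox was -0.048. Under normexp without spots under a bright background CPS (0.21) and FUL (0.22) in GNLox turned, GATA16 (0.00089) and NRT2.1 (0.065) in GATA17ox, GATA16 (-0.027) in GNL_LLM_AAAox against GNLox, GATA16 (-0.27), HANL2 (-0.10) and GATA29 (-0.67) in BdGATA6ox against GNLox, GATA16 (-0.29) and HANL2 (-0.32) in BdGATA6ox against GATA17ox and GATA16 (-0.53) in GNCox against GNLox. The mean of probes turned HAN in BdGATA6ox (0.35) and in BdGATA6ox against GATA17ox (0.34), GNC in GNCox (-0.14) and SAUR9 in GNC_LLM_AAAox against GNCox (-0.0019). GNC probe A_84_P212728 gave -1.41 in GNCox and -0.97 in GNC_LLM_AAAox. Slide as a fixed block turned PORA in BdGATA6ox (-1.97) and GATA17 in BdGATA6ox against GNLox (-0.073), and leaving out WT_batch1 replicate 1 turned WOX5 in GNLox (-0.11, and 3.35 without WT_batch1 replicate 3).

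Leaving out 1 array moved GNC_LLM_AAAox to 1724 to 2551 calls, GNL_LLM_AAAox to 2894 to 3827 (both lowest without WT_batch2 replicate A), GNL_LLM_AAAox against GNLox to 6339 to 10687 (lowest without WT_batch1 replicate 1), BdGATA6ox against GNLox to 7290 to 11801 (lowest without GNLox replicate 1) and GNCox against GNLox to 2592 to 7773, 743 to 2164 at least 2-fold (without GNLox replicate 1 and replicate 2). A replicate block gave 11296 calls for GNLox and 2731 for GNC_LLM_AAAox, and arrays of the same label did not pair (median correlation -0.009 in batch 1 and -0.040 in batch 2, 8 of 22 arrays closest to their own label).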

Other observations

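The comparisons here were added only after the data were seen, and the genes named were chosen after their values were seen.

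Some genes changed at least 2-fold in both LLM-mutated lines and beyond their unmutated counterparts in that direction, with the difference between mutated and unmutated line called for both GNC and GNL. There were 30 such genes higher and 51 lower, GNL itself among the higher. In 14 of the higher and 12 of the lower an unmutated line was called the same way, in 4 and 6 at least 2-fold, so not all are limited to the mutated lines. QQS, an orphan gene tied to starch content, rose in GNC_LLM_AAAox (2.66) and GNL_LLM_AAAox (3.07) and stood at -0.69 in GNCox and -0.56 in GNLox. ZFP10 rose by 2.92 and 2.97, and stood at -0.81 in GNCox and 1.42 in GNLox. Anthocyanin transcripts UF3GT, DFR, LDOX and 5MAT were among the higher, with 5MAT at 1.44 and 1.73, and at 0.96 in GNCox and 0.42 in GNLox. HAK5 fell (-2.97 and -4.92), and ARCK1 fell (-2.80 and -2.69) where the unmutated lines rose by 2.77 and 2.92. The receptor-like genes RLP28, RLP23, CRK6 and CRK14 and the factors WRKY50 and NAC090 also fell. Both mutated lines share the wild type of batch 2, so an error in those 3 arrays would appear in both. Those 3 lie on 1 slide with no mutated array, so slide differences could enter too. Slide-blocked calls in GNL_LLM_AAAox were 521 higher and 1370 lower, against 2380 and 2482. These genes have no slide-blocked value here.

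PUM7 was above background on both GNLox arrays, at 2.34 on replicate 1 and -0.91 on replicate 2. It was not above background on the other 20 (-9.62 to -8.31). Its 6 measured neighbours on the chromosome changed by at most 0.48. GATA16 and GATA15 fell in GNLox, GATA17ox and GNCox and rose again in the mutated line over GNCox (1.45 and 1.2).

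The wild types of the batches differed in 6693 genes, 1118 of them at least 2-fold.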
